A study of Mus musculus with 6 samples.

How the data were processed

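UTX CUT&Tag was measured in 6 samples, 3 WT and 3 UTX-deficient, from sorted progenitor CD8 T cells of mouse pancreatic lymph nodes, and 1 table with the authors' own comparison was used. Per the submitters' processing notes, the tools were FastQC, cutadapt, Bowtie2, SAMtools, Picard, MACS2 and DiffBind with build mm10, and their roles and versions are not given in the sources used here. Per the file headers, the table is a DiffBind report with a mean concentration over all samples, a concentration per group, a fold, a p-value, an FDR, a peak number and a gene symbol per site. The concentrations are log2 values of mean normalized reads, with 0 as the lowest value, and the fold is a log2 value as deposited, negative where WT is higher. The p-value and the FDR are the authors' own, and each deposited FDR is under 0.05. The ratio of FDR to p-value gives 8293 tests behind the deposited values, of which 1554 are outside the table. Row numbers in the table run up to 10831, so the authors' set may have held further sites that are not among these tests. Whether peaks were called per sample or on pooled samples is not stated, and IgG control libraries were not used here.

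Samples were grouped by the genotype in the labels. The main result reads the authors' fold and FDR at a threshold of 0.05, with no test per site of its own. Sites were summarised by direction, with an exact (Clopper-Pearson) 95% interval for the share higher in WT. Gene symbols were matched to a reference annotation of GRCm38.p6, the assembly of mm10, with older symbols resolved through its synonyms. In all, 6677 sites matched and 6669 could be placed against the assigned gene. At 70.3% of the placed sites the nearest gene end of the annotation was that of the assigned gene, and at the rest another gene end lay nearer. Results by gene list and family rest on the authors' assignment. The annotation holds no strand, so transcription starts could not be placed, and the distance from the middle of a site to the nearer end of its assigned gene stands in for distance to a start. Sites within 1 kb of either end were compared between directions by Fisher's exact test. Sites per chromosome were compared with the number expected from length (the largest gene end on the chromosome) by exact binomial tests with Benjamini-Hochberg adjustment.

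Before the data were examined, 14 gene lists and the rule for named sites were fixed. The lists cover progenitor, effector and exhaustion genes, T cell receptor signalling and lineage, H3K27 and H3K4 methylation machinery, developmental regulators, interferon response, cell cycle, ribosomal and housekeeping genes, and markers of B cells, myeloid and dendritic cells, CD4 and regulatory T cells, natural killer and innate lymphoid cells, and pancreatic, stromal and endothelial cells. The named sites are the one at Kdm6a, the 10 with the largest fold in each direction, the 5 with the smallest FDR in each direction, up to 4 members of each list by FDR, and the 5 genes with the most sites. Gene models known only by a number were passed over in the first choices by fold and FDR. A list was tested by a two-sided Fisher's exact test on its genes with a site higher in WT against all 21900 protein-coding genes, with Benjamini-Hochberg adjustment over the 14 lists. Sites higher in UTX-deficient cells touched 19 protein-coding genes, fewer than the 20 set as the minimum for testing the lists. On simulated lists of 35 genes over 21900 genes, the list test called 99.6% of lists with a planted odds ratio of 5 and 1.11% of the others.

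After the data had been examined, reads per library were recovered from the concentrations. The antilog of a group's concentration times 3 is a sum of 3 whole read numbers, each multiplied by what 1 read of its library is worth, and the mean over all samples gives the sum where a group lies at the floor. The worth of 1 read was found from the table, and each sum was then solved within its rounding error. WT sums had exactly 1 solution at 6728 sites and several at 11, and UTX-deficient sums had exactly 1 at 6739. Sums shifted at random by 0.05 to 0.45 normalized reads were solved in 2.91% of cases in WT and in 0% in UTX-deficient cells. The recovered depths summed to 6 over the 6 libraries, the value for library sizes divided by their mean. Tested on 3 simulated tables of 6739 sites, the recovery solved at least 6673 sites and none wrongly. Each simulated table was built with a near-empty UTX-deficient library whose reads lay in a few sites alone. The simulations therefore do not test whether such a library could be inferred where there is none. Depth per library is in the report, and 1 read of the shallowest UTX-deficient library is worth 173.2 normalized reads. Such reads without molecular identifiers are not independent molecules. The intervals given are on numbers of sites and of list genes, not on reads, and treat sites or genes as independent.

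The recovered reads were tested with limma 3.58.1 in R 4.3.3 on log2(normalized reads + 1), with a trend in the prior variance and Benjamini-Hochberg adjustment over 8293 tests, sites outside the table entering with the largest possible p. The prior variance came from sites already selected for differing, so these calls are no independent test. On simulated reads at 6728 sites with the depths of the 6 libraries, limma called 2.5% of sites lowered 8-fold. Without the shallowest UTX-deficient library it called 100% of these, 23% of sites lowered 2-fold and 11 of 6328 unchanged sites. The simulation let the shallowest UTX-deficient library hold reads at any site, while in the data it held 0 reads at the 6707 solved sites higher in WT. The 2.5% therefore does not describe the calls with all 6 libraries on the data, which rest on sites where that library held 0 reads. The simulated knockout also stayed at the WT level at 6328 of the 6728 sites, with adjustment over 6728 tests. In the data the other UTX-deficient libraries held medians of 2 and 3 reads per site higher in WT. The other simulated shares do not describe the calls on the data either. Alternatives fixed beforehand were FDR 0.01 and 0.001, a minimum log2 fold of 1, leaving out the lowest 25% of sites by mean concentration, autosomes or standard chromosomes alone, distances of 1, 3 and 10 kb, 10000 random lists matched on gene length, and expected site numbers from gene numbers. Those added later were limma on recovered reads, a pseudocount of 0.1, each library left out in turn, a test of the progenitor against the effector list, and gene families by symbol. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.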

Results

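Binding of UTX, the histone H3 lysine 27 demethylase encoded by Kdm6a, was profiled by CUT&Tag with an antibody against UTX in progenitor CD8 T cells (Ly108 positive, CXCR6 negative) sorted from pancreatic lymph nodes. The mice were NY8.3 animals, whose T cells carry a transgenic receptor for an islet antigen. The groups were 3 samples from WT mice and 3 from mice lacking UTX in T cells. The question was which regions UTX binds directly, with the UTX-deficient cells as the control for antibody specificity. Group values for 6739 sites of 401 bp that differed between the genotypes were given in the authors' deposited table. Whole reads per library were recovered from those group values for 6728 sites, and the recovered libraries are ranked by depth because they carry no replicate number. Relative to a mean of 1 over the 6 libraries, depth was 1.28, 0.916 and 0.792 in WT and 1.93, 1.07 and 0.00577 in UTX-deficient cells. The last library was close to empty, 335 times shallower than the deepest of its group. In the sites higher in WT, the WT libraries held 344721, 273989 and 198453 reads, and the UTX-deficient libraries held 15301, 26472 and 0.

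**Figure D1:**
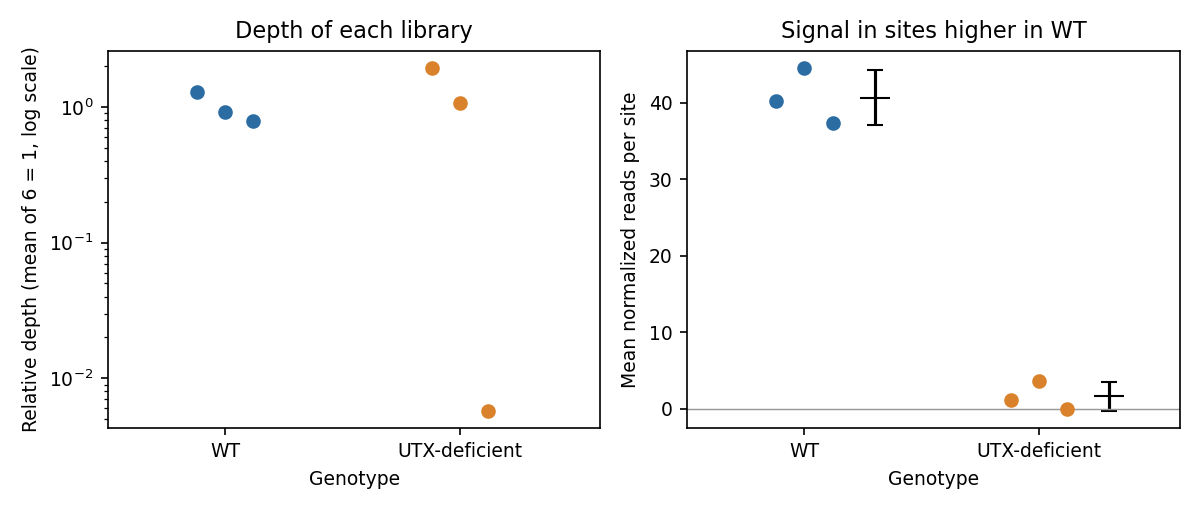
The left panel plots the relative depth of each recovered library by genotype on a log axis, and the right panel plots its mean normalized reads per site over 6707 sites higher in WT. Crosses and bars give the mean and SD of 3 libraries, 40.7 ± 3.65 in WT and 1.62 ± 1.88 in UTX-deficient cells, and 1 UTX-deficient library lies at a depth of 0.00577.

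The UTX signal was lower in UTX-deficient cells at nearly all differing sites, among them sites at the progenitor genes Bach2, Klf2, S1pr1 and Ccr7, the T cell receptor genes Cd3d, Cd247 and Lck, and the gene of the related H3K27 demethylase, Kdm6b. In the authors' deposited table, a total of 6718 sites were higher in WT and 21 were higher in UTX-deficient cells. The share higher in WT was 99.7% (exact 95% interval 99.5 to 99.8, treating sites as independent, which they are not). The median log2 fold of the sites higher in WT was -3.51 in the authors' deposited table, with quartiles of -4.06 and -2.91. Per library, the mean over these sites was 40.7 ± 3.65 normalized reads (SD, n = 3) in WT and 1.62 ± 1.88 (SD, n = 3) in UTX-deficient cells. Each WT library, from 37.4 to 44.6, lay above each UTX-deficient library, at 3.68, 1.18 and 0. No exact permutation test of 3 against 3 libraries can give a two-sided p under 0.1, and these sites had been selected for being higher in WT. Without the near-empty library, WT exceeded UTX-deficient cells 16.8-fold. By limma on the recovered reads, 6707 sites were higher in WT and 20 in UTX-deficient cells with all 6 libraries, against 6706 and 4 without the near-empty one.

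The Kdm6a gene itself carried 1 site, on chromosome X from 18162206 to 18162606, 1544 bp from an end of the gene. The authors' deposited table gives it a log2 fold of -2.73 (FDR 7.14e-11), and the recovered reads were 65, 48 and 35 in WT and 8, 12 and 0 in UTX-deficient cells. The labels do not say which part of Kdm6a was deleted, so this site does not check the genotype. The largest decrease in the authors' deposited table was at a site assigned to Rps6ka1, a ribosomal S6 kinase gene, 33236 bp from the gene, with a log2 fold of -6.36. That site held 82, 83 and 61 reads in WT and 0 in every UTX-deficient library, so its fitted fold is no bound on the change. Next in the authors' deposited table came Skil, a repressor of SMAD signalling, at -5.94, Zfp36l1, an mRNA decay factor, at -5.89, and Fkbp5, a glucocorticoid-induced chaperone, at -5.84. That Fkbp5 site lay 36744 bp from the gene, and the other Fkbp5 site, which overlapped an end of the gene, had a log2 fold of -2.69. Msh5, Fam240a, Cd4, Fmnl1, Irf2bpl and Tle5 followed in the authors' deposited table with log2 folds from -5.77 to -5.59. The Fam240a and Irf2bpl sites lay outside these genes, 6772 and 46631 bp from an end of the gene. The smallest FDRs in the authors' deposited table were at Tha1 (2.12e-33), Sirt2 (6.1e-32), Ssc4d (1.5e-31), Hspa8 (8.02e-30) and Prex1 (1.56e-28). At Sirt2, which encodes an NAD-dependent deacetylase, the reads were 296, 225 and 158 in WT and 7, 7 and 0 in UTX-deficient cells.

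Genes of the progenitor program had a site higher in WT far more often than protein-coding genes as a whole. A site higher in WT was assigned to 4837 of 21900 protein-coding genes (22.1%) and to 23 of the 30 genes of the progenitor or stem-like list (76.7%; odds ratio 11.6, Fisher's exact test, two-sided, adjusted p = 2.15e-09 over 14 lists). At Klf2, a transcription factor of quiescence and trafficking, the site 130 bp from a gene end held 177, 136 and 98 reads in WT and 14, 17 and 0 in UTX-deficient cells. S1pr1, the receptor for exit from lymph nodes, Ccr7, a homing receptor, and Cd28, a costimulatory receptor, had log2 folds of -3.49, -3.11 and -3.23 in the authors' deposited table. That S1pr1 site lay 27517 bp from the gene. Bach2, a repressor of effector differentiation, had the most sites of any gene, 10, followed by Foxp1 with 8 and by 5 genes with 7 each, of which Ago2, Galnt2 and Klf13 are named because ties were broken by alphabet. The 10 Bach2 sites on chromosome 4 reached from 32149152 to 32588594, and each was lower in UTX-deficient cells, with log2 folds from -3.86 to -2.33 in the authors' deposited table. Tcf7, which encodes the progenitor factor TCF-1, had 4 sites, and Slamf6, which encodes the sort marker Ly108, had 1 with a log2 fold of -3.73 in the authors' deposited table. Tcf7 and Slamf6 were named after their values had been seen. When sites farther than 1 kb from a gene end were left out, 9 of the 30 progenitor genes had a site and the call was lost (odds ratio 2.38, Fisher's exact test, adjusted p = 0.066).

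**Figure D2:**
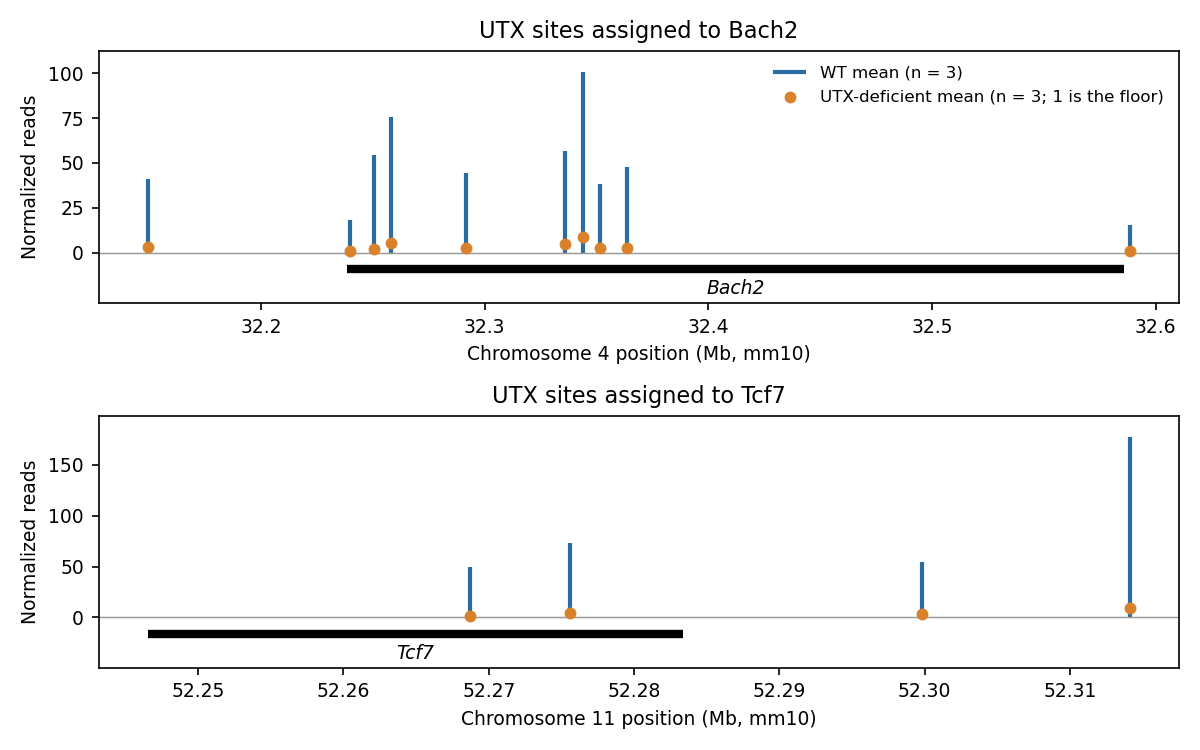
Mean normalized reads in WT (blue lines, 3 libraries) and UTX-deficient cells (orange points, 3 libraries) are plotted against chromosome position in Mb for the 10 sites assigned to Bach2 and the 4 assigned to Tcf7, with the gene as a black bar. Every site is lower in UTX-deficient cells, and points at 1 lie at the floor that the table's lowest concentration of 0 sets.

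The list of T cell receptor signalling and lineage genes had the highest share, with a site at 34 of 38 genes (89.5%; odds ratio 30.2, Fisher's exact test, adjusted p = 1.81e-17). Cd3d and Cd247, which encode chains of the receptor complex, had log2 folds of -4.70 and -4.45 in the authors' deposited table, Lck, the proximal kinase, had -4.20 at a site outside the gene, and Nfatc3 had -4.15. With sites within 10 kb of a gene end the list kept its call at 22 of 38 genes (57.9%, odds ratio 5.78), below the 63.3% of the progenitor and the methylation machinery lists, and within 1 kb its odds ratio was 5.01. Sites higher in WT were also frequent at the H3K27 and H3K4 methylation machinery, with a site at 19 of 30 genes (63.3%; odds ratio 6.11, Fisher's exact test, adjusted p = 4.91e-06). Kdm6b, the paralogue of Kdm6a, Jarid2, a Polycomb cofactor, Setd1b, an H3K4 methyltransferase, and Ep300, a histone acetyltransferase, had log2 folds of -4.70, -4.32, -4.11 and -4.98 in the authors' deposited table. None of the 72 developmental regulators of the Polycomb target type, such as Hox, Pax and Sox genes, had a site (0%, exact 95% interval up to 4.99%; Fisher's exact test, adjusted p = 1.27e-07).

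Effector or cytotoxic genes had a site less often than progenitor genes, 18 of 44 (40.9%; odds ratio 2.45, Fisher's exact test, adjusted p = 0.015), and the difference between the lists gave p = 0.00394 by Fisher's exact test in a comparison chosen after the values were seen. Fasl, Runx3, Ifng and Prf1 had log2 folds of -4.59, -4.86, -4.38 and -3.88 in the authors' deposited table. The only Ifng site lay 21859 bp from the gene. This Fasl site lay 13907 bp from its gene, and another Fasl site, 1494 bp from it, had a log2 fold of -4.61. The median gene length was 36456 bp in the progenitor list and 11461 bp in the effector list. Against random lists matched on gene length both calls were kept, with odds ratios of 8.50 and 2.36 (adjusted permutation p = 0.0007 and 0.0163). The effector call was lost with sites within 10 kb of a gene end (odds ratio 1.57) and at FDR 0.01 (odds ratio 1.93). It turned with sites within 1 kb (odds ratio 0.711). Of the exhaustion or inhibitory receptor list, 12 of 26 genes had a site (46.2%; odds ratio 3.03, Fisher's exact test, adjusted p = 0.0165). Nr4a1 and Nr4a3, orphan nuclear receptors induced by receptor signalling, Socs1, a suppressor of cytokine signalling, and Cblb, a ubiquitin ligase, had log2 folds of -4.63, -4.70, -4.72 and -3.00 in the authors' deposited table. Pdcd1, Lag3 and Havcr2, named after the values were seen, had no differing site in the authors' deposited table. Cell cycle genes had a site at 14 of 36 (38.9%; odds ratio 2.25, Fisher's exact test, adjusted p = 0.043), among them the cyclin genes Ccne1, Ccnd2 and Ccnd3 and the kinase gene Cdk4. The exhaustion and cell cycle calls were lost against random lists matched on gene length, with odds ratios still at 2.57 and 2.09 (adjusted permutation p = 0.0508 and 0.0644). Ribosomal and housekeeping genes had a site at 16 of 40 (40%; odds ratio 2.36, Fisher's exact test, adjusted p = 0.0231), with Actb, Polr2a and Hsp90ab1 at log2 folds of -5.02, -4.59 and -4.86 in the authors' deposited table.

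Interferon response genes did not pass the test, with a site at 11 of 29 (37.9%; odds ratio 2.16, Fisher's exact test, adjusted p = 0.107), among them the receptor genes Ifngr1 and Ifnar1 and the factor genes Irf1 and Irf9. None of the lists for other cell types passed. B cell markers had a site at 1 of 13 genes, Pou2af1 (adjusted p = 0.375, Fisher's exact test), and myeloid and dendritic markers at 2 of 20, Cebpb and Spi1 (adjusted p = 0.358, Fisher's exact test). CD4 and regulatory T cell markers had a site at 5 of 16, among them Cd4, Izumo1r, Ikzf4 and Il2ra (adjusted p = 0.399, Fisher's exact test). The Cd4 site held 97, 85 and 48 reads in WT and 0, 2 and 0 in UTX-deficient cells. Natural killer and innate lymphoid markers had a site at 3 of 15, Gata3, Tyrobp and Kit (adjusted p = 1.0, Fisher's exact test), and pancreatic, stromal and endothelial markers at 1 of 20, Pecam1 (adjusted p = 0.14, Fisher's exact test). The sites of Gata3, Tyrobp and Kit lay outside these genes, 262841, 19286 and 135199 bp from an end of the gene. None of the 15 natural killer and innate lymphoid markers had a site within 10 kb of a gene end. Il2ra is also on the effector list, Gata3 on the T cell receptor list and Kit on the progenitor list. The background of all protein-coding genes includes genes silent in T cells, and the table holds differing sites alone, so these shares do not separate UTX binding from gene activity.

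**Figure D3:**
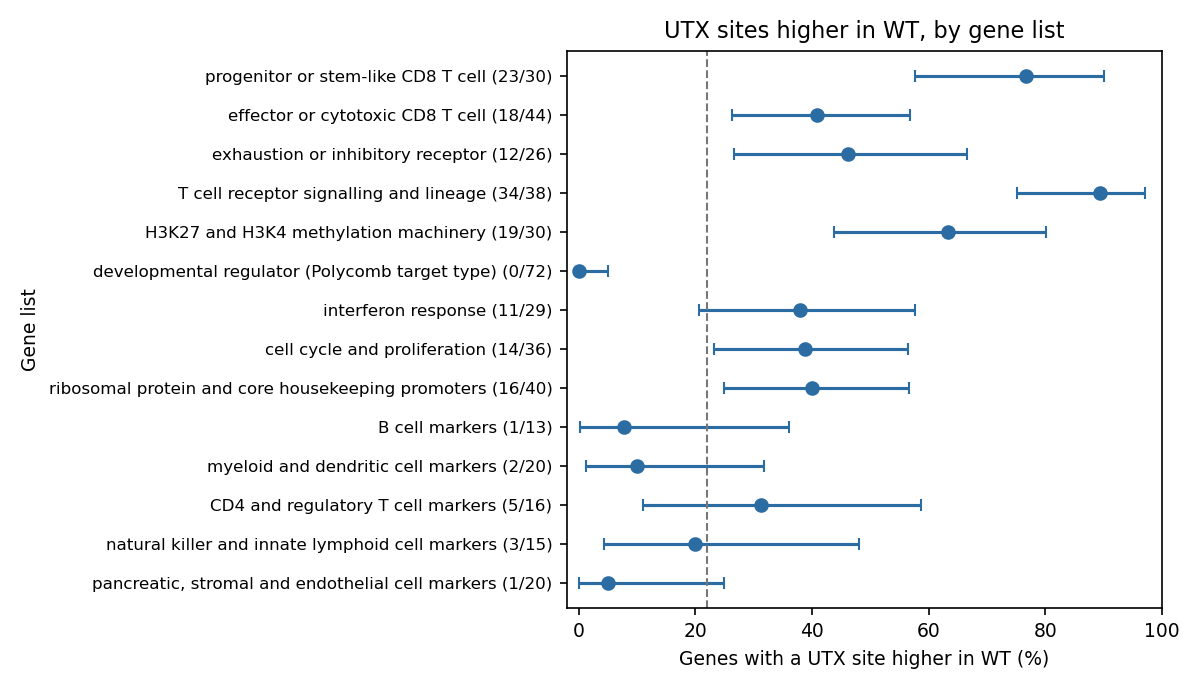
The percentage of each list's genes with a UTX site higher in WT is plotted with its exact 95% interval, with counts in the labels, and the dashed line marks the 22.1% of all protein-coding genes. The T cell receptor list reaches 89.5% and the progenitor list 76.7%, while the developmental regulators lie at 0%.

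Sites higher in WT lay close to genes. Of 6648 such sites placed against the assigned gene, 76.4% overlapped it and 53.2% lay within 1 kb of either end of it, with a median distance of 644 bp to the nearer end. None of the 21 sites higher in UTX-deficient cells lay within 1 kb (Fisher's exact test, two-sided, p = 1.25e-07), and their median distance was 48864 bp. That test counts sites as independent, while 20 of the 21 rest on reads of the near-empty library, so it compares sets of sites and not genotypes. By chromosome length, chromosome 11 held 621 sites, 2.06 times the expected number (exact binomial test, adjusted p = 2.48e-61), and 1.26 times the number expected from its protein-coding genes. Chromosome X held 103 sites, 0.245 times the expected number by length (exact binomial test, adjusted p = 3.18e-79) and 0.348 times by genes, and no site lay on chromosome Y. The chromosome tests treat sites as independent and count chromosome Y in the expected numbers. They take no account of the sex of the mice or of the copies of X per cell, so they do not single out UTX binding.

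Of the 21 sites higher in UTX-deficient cells, an internal site of Lck was the best covered by the well-sequenced libraries. It lay on chromosome 4 from 129560006 to 129560406, with a log2 fold of 2.27 (FDR 0.0182) in the authors' deposited table. It held 15, 5 and 2 reads in WT and 41, 59 and 0 in UTX-deficient cells, while both other Lck sites fell. The one from 129573586 to 129573986, which spans an end of the gene with its middle 145 bp beyond it, held 60, 60 and 31 reads in WT and 4, 8 and 0 in UTX-deficient cells, and the one outside the gene, from 129575174 to 129575574, held 118, 86 and 58 in WT and again 4, 8 and 0 in UTX-deficient cells. The largest log2 fold in the authors' deposited table, 25.38, belonged to a site 9788 bp from Gzmf, a granzyme gene, whose reads were 49 in the near-empty library and 1 in all other libraries together. Auts2, Htr1a, Mir344b, Antxr2, Il34, Nol4, Efr3a, G6pd2 and Man1a followed with log2 folds from 5.93 down to 4.83 in the authors' deposited table. At 20 of the 21 sites, all except the one in Lck, the near-empty library supplied at least 94.0% of the normalized signal of its group, a share that 1 read there gave at Elavl4. At Lck, Elavl4, Nol4 and Auts2, both other UTX-deficient libraries lay above each WT library, and these were the 4 of the 21 sites that limma called higher in UTX-deficient cells without the near-empty library. The site assigned to Rapgef2 was called lower in that setting, with a log2 difference of -1.07. With all 6 libraries limma did not call the Lck site, whose log2 difference was 0.70, against 2.41 without the near-empty library. The higher Lck site, Elavl4 and Rapgef2 were named after their values had been seen.

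**Figure D4:**
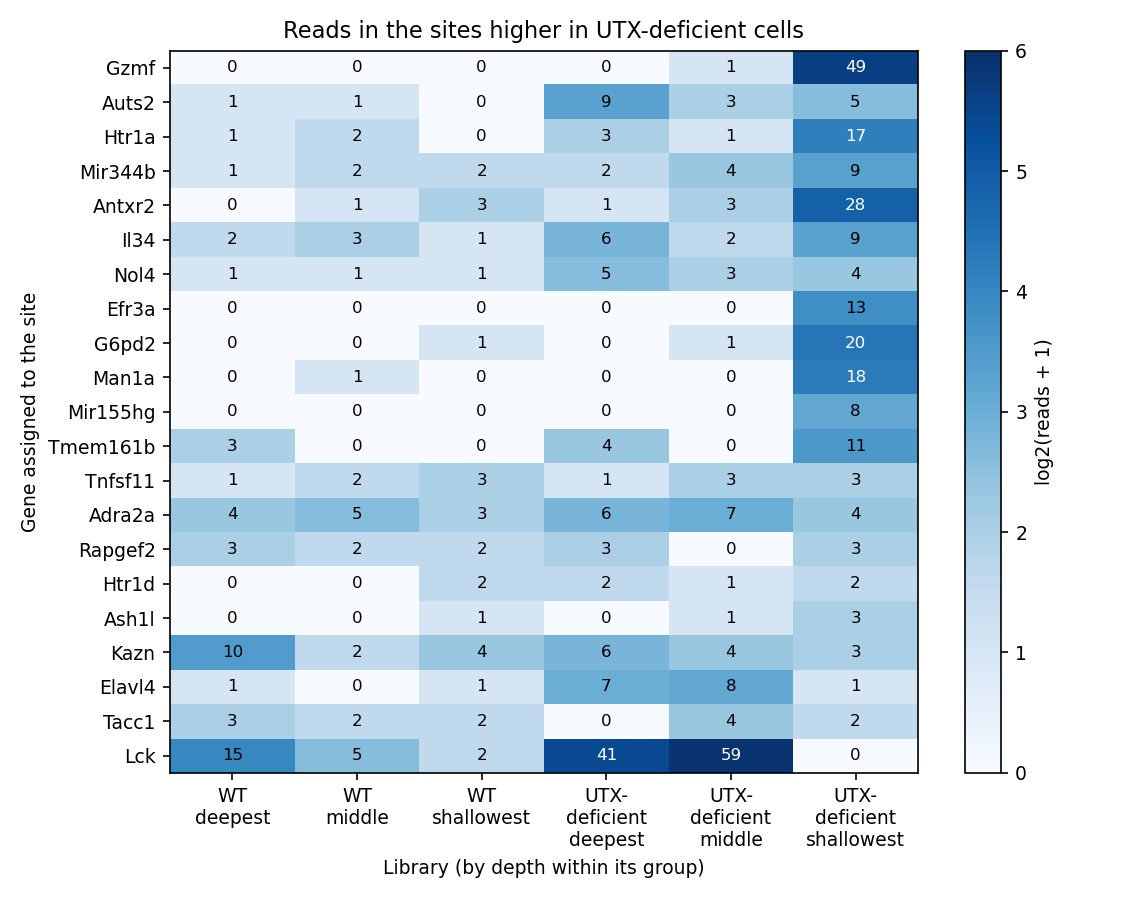
Recovered reads are printed for each of the 21 sites higher in UTX-deficient cells (lines of the grid, by assigned gene) and each library (columns, by depth within its group), with shading by log2(reads + 1). The shallowest UTX-deficient library holds reads at every site except Lck, up to 49 at Gzmf, and at Lck the other UTX-deficient libraries hold 41 and 59.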

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

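All tests in this part were chosen after the results had been seen, and the first, with its bounds set when the limma values were known, replaced an earlier test on the share of signal held by the near-empty library, which 1 read there settles. Reads of the near-empty UTX-deficient library, which the main comparison uses only inside a group mean, came to 212 in the sites higher in UTX-deficient cells. The WT libraries held 81 reads in the same 20 sites, which at the depth of the near-empty library would be 0.157 reads.

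The sites higher in UTX-deficient cells were weighed first. Without the near-empty library the log2 difference by limma was under 1 at 18 of the 20 sites that hold its reads, so reads of 1 library, scaled up, are a candidate explanation for these calls, though at 11 of the 20, from Gzmf with 49 reads to Ash1l with 3, that library held more reads than any other before any scaling, and why they gathered there was not tested. By the same limma values, and so not as separate evidence, a gain shared by the other UTX-deficient libraries is argued against for the 20 sites as a set, since their median log2 difference by limma without that library was 0.15, against 4.78 for their median fold in the authors' deposited table. A smaller gain at Auts2, Elavl4 and Nol4, which limma still called higher without that library, stays open, while 7 of the 20 sites showed no positive difference and Rapgef2 was called lower. These sites held at most 9 reads in either of the other UTX-deficient libraries.

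The lower signal of UTX-deficient cells at 6718 sites was weighed next. A pull of the near-empty library on the group mean is argued against, since the median log2 difference by limma without it was -3.65. Shallower sequencing of the knockout libraries is argued against as well, since reads per site and unit of depth were still 11.1 times higher in WT than in the better of the other UTX-deficient libraries. A lower yield of the knockout reactions cannot be told apart from loss of the target of the antibody, because yield and genotype go together, and the other UTX-deficient libraries themselves differed 3.12-fold in reads per site and depth. Among the 10 splits of the 6 libraries into groups of 3, the real one gave 6727 limma calls and the highest other 0. Only the real split itself gave as many, 1 of the 10, a number of splits too small for a share under 0.05. The sites had also been selected for differing under the real split, so few calls in the others were settled in advance and decide nothing.

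The internal Lck site that was higher in UTX-deficient cells was weighed last. The near-empty library held 0 reads there, which argues against scaling of that library. A Cre transgene driven by an Lck promoter fragment could add copies of the sequence and so reads, but both other Lck sites fell, with log2 folds of -3.33 at the site that spans an end of the gene and -4.20 at the one outside it in the authors' deposited table. A fragment that held either of these sites would have added reads there too, but nearly every site fell and the extent of any fragment is not known, so extra copies and a local gain of binding cannot be told apart here. The labels name no Cre driver, and a gain of binding was not tested otherwise.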

How the results depend on the processing

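The limma and leave-one-out settings were chosen after seeing the data, and the others before. The sites higher in WT numbered 4902 to 6717 under the other thresholds and filters and 6699 to 6707 by limma on recovered reads. Those higher in UTX-deficient cells numbered 21 in the main result, 6 at FDR 0.001, 13 by limma with a pseudocount of 0.1, and 4 to 20 with each library left out in turn, the 4 without the near-empty library. Odds ratios of lists that crossed the threshold for the adjusted p were, within 1 kb of a gene end, 2.38 for progenitor genes (lost) and 0.711 for effector genes (turned, not past the threshold). Within 10 kb they were 1.57 for effector genes (lost), 2.56 for interferon genes (gained) and 0 for pancreatic, stromal and endothelial markers (gained, as a depletion). At FDR 0.01 they were 1.93 for effector genes (lost) and 0 for myeloid and dendritic markers (gained, as a depletion). Against random lists matched on gene length they were 2.57 for exhaustion genes and 2.09 for cell cycle genes (both lost). Odds ratios of lists past the threshold in no setting turned from 1.604 to 0 for CD4 and regulatory T cell markers within 1 kb and from 0.882 to 1.03 for natural killer and innate lymphoid markers at FDR 0.01. The cause was not tested in any of these. The other 81 alternatives for the main results kept their direction and side of the threshold or their size. All 504 limma alternatives for the 63 named sites higher in WT kept their direction and call. With 6699 to 6707 sites called in every limma setting, all selected beforehand for differing, this could hardly have come out otherwise. The difference at Man1a ranged from -0.35 to 5.45 with each library left out, turning without the near-empty library, as did sites outside the rule for named sites at Rapgef2 (-1.07), Tacc1 (-0.62), Kazn (-0.33) and Tnfsf11 (-0.32). No paired analysis was possible because the table holds group values and the recovered libraries carry no replicate number. FDR 0.1 and an unadjusted p could not be run on a table that ends at FDR 0.05, all sites have 1 width so no width filter applied, and count tests were not run. Few reads per site in UTX-deficient cells, a median of 2, 3 and 0 per library, limit how well a remaining signal can be ranked.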

Other observations

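Gene families by the stem of the symbol were compared with all protein-coding genes after the data had been seen, as 360 families of at least 8 genes. Of the Kdm lysine demethylase family, 13 of 18 genes had a site higher in WT (odds ratio 9.19, Fisher's exact test, adjusted p = 0.000414 over the families). Sites were also frequent at the Dennd genes, regulators of Rab GTPases, with 12 of 16 (odds ratio 10.6, Fisher's exact test, adjusted p = 0.000441), at the Rab genes themselves, with 32 of 69 (odds ratio 3.06, Fisher's exact test, adjusted p = 0.000414), at the Cnot genes of the deadenylase complex, with 9 of 11 (odds ratio 15.9, Fisher's exact test, adjusted p = 0.00147), and at the Chd chromatin remodellers, with 8 of 10 (odds ratio 14.1, Fisher's exact test, adjusted p = 0.00454). None of 1110 Olfr olfactory receptor genes (Fisher's exact test, adjusted p = 6.7e-122) and none of 355 Vmn vomeronasal receptor genes had a site. The family tests were not matched on gene length, and their background again includes genes silent in T cells. Several Kdm genes are also on the methylation machinery list, so the Kdm result is not separate from that list.

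At sites higher in WT, the mean of the deeper UTX-deficient libraries was at a median of 5.75% of the WT mean, with quartiles of 3.86% and 8.26%. It exceeded 20% at 32 of 6707 sites. All of these sites had been selected for being lower in UTX-deficient cells. Sites that kept more signal are thus mostly left out of the median and of this number. The highest share, 50.7%, was at a site assigned to 1600014C10Rik on chromosome 7, from 38183522 to 38183922, with 52, 34 and 31 reads in WT and 35, 23 and 0 in UTX-deficient cells. Next came a site assigned to Pisd-ps3 on an unplaced contig, at 39.4%. Both were named after their values had been seen.

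Across sites, which are not independent replicates, Spearman's rho of normalized reads was 0.885 between the deepest and the middle WT library and 0.361 between the deepest and the middle UTX-deficient library. The middle UTX-deficient library followed the WT mean with a rho of 0.625 and the deepest with 0.277. These values are not at like read numbers. In the sites higher in WT, the UTX-deficient pair held medians of 2 and 3 reads per site, against 39 and 31 in the WT pair. The middle UTX-deficient library held 26472 reads there and the deepest 15301. A single read of the near-empty library adds 57.7 normalized reads to the mean of its group, more than the WT mean of all but 1152 of the sites higher in WT. In the sites higher in WT, 142.5 reads would be expected from the near-empty library at the rate of the middle UTX-deficient library and 45.7 at the rate of the deepest, and 0 were recovered. At all but the 1152 sites, a read of that library would have put the mean of its group above the WT mean. Whether sites with such a read would have been called higher in WT was not tested, at these sites or at the 1152. The sites had been selected for being higher in WT, so the 0 does not decide whether that library lacked reads there.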
